A study of Allium cepa with 12 samples.

How the data were processed

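RNA was measured in 12 libraries from bulb tissue (outer and inner scales) of onion, Allium cepa cultivar Don Victor. Bulbs injected with Salmonella enterica serovar Newport and uninoculated bulbs were sampled at day 1 and day 7, with 3 libraries in each of the 4 groups, and the labels describe the bulbs of a group as independent. The labels name no bulb injected without bacteria, so the wound and the bacterium were not separated by this design. Per the labels' protocols, polyadenylated RNA was selected with oligo(dT) beads, the strand was marked with dUTP, and libraries were sequenced as DNA nanoballs on a DNBSEQ instrument. Whether the counting used the strand is not given in the sources used here, so genes that overlap on opposite strands are uncertain.

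The authors deposited 1 transcript table per library. Per the file headers, each transcript had a gene ID, a length, an RSEM expected count, FPKM, TPM and the percent of its gene's expression (isoform percent). RSEM splits a read that fits several transcripts between them, so the expected counts of the deposited tables need not be whole. The submitters' processing notes name fastp, HISAT2, StringTie, Cufflinks, Bowtie2, RSEM and DESeq2 1.20.0, with no role for each. Genome build and annotation version are not given in the sources used here. Each table listed only transcripts with a value above 0, so a transcript missing from a table was taken as 0. Over the 12 libraries the tables held 82230 transcripts of 72432 genes. Of these genes 61598 were reference models, 99.1% of whose lengths were multiples of 3 (coding length), and 10834 were assembled loci, 817 of them long non-coding RNA (lncRNA) loci. The files do not pair gene IDs with names, descriptions, coordinates or sequence, and 0 genes could be matched to a name. The 39 gene lists fixed before the data were examined (defence proteins, cell wall enzymes, organosulfur and flavonoid enzymes, and markers of sprout leaf, dividing tissue and RNA quality) could therefore not be filled or tested.

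Expected counts were summed per gene and rounded to whole numbers. Totals lay between 17273800 and 21493366 per library. The main test was edgeR 4.0.16's quasi-likelihood F-test in R 4.3.3, with TMM factors, robust dispersion and 1 fit of the 4 group means over the 12 libraries. The default filter of edgeR kept 32211 genes, and the common biological coefficient of variation was 0.52. Adjusted p-values are Benjamini-Hochberg values over these genes, and a gene was called at an adjusted p under 0.05. The 5 contrasts were inoculated against uninoculated at each day, the difference between those effects, and day 7 against day 1 in each treatment. The standard error of a fold change was taken as its size divided by the square root of its F statistic. CPM values are expected counts scaled to the library's total over the tested genes times its TMM factor. The 5 CPM filter, the 266-gene set and the comparisons of the day 1 libraries numbered 1 with other libraries used the plain library total. Principal components used log2 CPM with a prior count of 2. Single values per library were compared by two-sided exact permutation tests, whose smallest p with 3 against 3 is 0.1.

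Named genes followed a rule fixed before the data were examined: the largest fitted changes among called genes with non-overlapping groups, a mean of at least 10 CPM in the higher group and at least 10 reads in the lower group. For the difference between days the rule was the smallest adjusted p. As the IDs have no names, at most 2 IDs per direction are printed. A gene is described as having whole counts if its expected counts lay within 0.02 of a whole number in all 12 libraries. A small allowance for rounding was added per transcript. The remaining genes shared at least some reads with further genes, and how many reads was not measured. Whole counts were found for 11178 of the tested genes (34.7%). A further 785 genes of the tables lay in sets with identical counts and length.

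The fit was tested on simulated data: counts of 32211 genes were drawn with 50 genes changed per size. For the day 1 contrast it recovered 2%, 40%, 64% and 82% of genes changed by 1, 2, 3 and 5 on the log2 scale, with 0 false calls. For day 7 it recovered 0%, 24%, 52% and 90%, with 2 false calls. For the difference between days it recovered 0%, 10%, 30% and 72%, with 5 false calls. So few changed genes make the adjusted threshold stricter than in the real comparisons. Counting error is small beside this spread between bulbs, except for genes near 0 reads.

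Alternatives fixed before the data were examined were RLE size factors, no composition factor, DESeq2 1.42.0, limma 3.58.1 (voom on counts, and trend on log2 of FPKM plus 1 or 0.1), other low-count filters, transcripts in place of genes, other thresholds, a fit of each day alone, the replicate number as a block, removal of the 10 most abundant genes, and removal of each library in turn. Alternatives chosen after seeing the data were genes with whole counts only, identical genes summed, removal of both day 1 libraries numbered 1, a refit with these libraries exchanged between their groups, other detection minimums, and all tests of the lncRNA loci as a list. Thinning of the libraries for the count of detected genes was also chosen then. Tables were handled with Python 3.11.15, pandas 2.3.3 and SciPy 1.17.1.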

Results

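The transcriptome of onion bulb scales was measured by RNA-seq at 1 and 7 days after injection of Salmonella enterica serovar Newport, a bacterium of animals and humans rather than an onion pathogen, and in uninoculated bulbs of the same days. Each of the 4 groups held 3 bulbs, 1 library per bulb. Total expected counts per library were 19062085 to 20297124 in uninoculated day 1 bulbs, 17273800 to 21493366 in inoculated day 1 bulbs, 17347810 to 19628530 in uninoculated day 7 bulbs and 18737667 to 19255827 in inoculated day 7 bulbs. The totals of inoculated and uninoculated libraries did not differ detectably (exact permutation test, p = 1.0 at day 1 and 0.8 at day 7, smallest possible 0.1). The files do not pair gene IDs with names, so genes are given by ID and by class.

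The first principal component held 58.7% of the variance and separated the treatments at both days. Its scores ran from -201.3 to -119.6 in the 6 uninoculated libraries and from 129.2 to 198.2 in the 6 inoculated ones. Replicate 1 of both day 1 groups lay apart from its group. Uninoculated day 1 replicate 1 scored 211.1 on the second component, against 24.2 and 58.3 in replicates 2 and 3. Inoculated day 1 replicate 1 scored -81.4, against 24.1 and 66.0. Spearman correlations between libraries of a group reached down to 0.873 in uninoculated and 0.871 in inoculated day 1 bulbs, and lay between 0.962 and 0.964 in uninoculated and between 0.930 and 0.947 in inoculated day 7 bulbs.

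**Figure D1:**
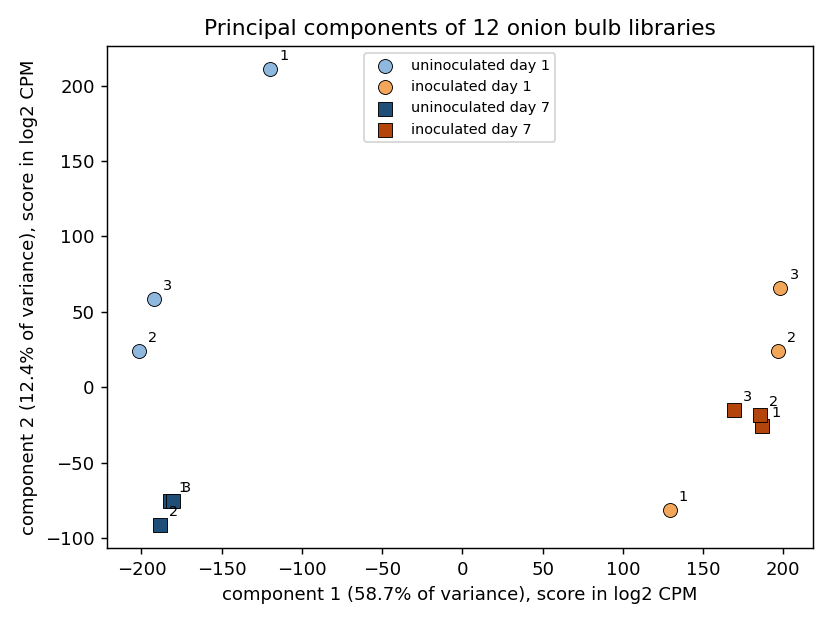
Scores of the 12 libraries on the first (x axis, 58.7% of variance) and second (y axis, 12.4%) principal component of log2 CPM; points are libraries, colours are groups, numbers are replicates. Treatments separate along x, and replicate 1 of both day 1 groups lies apart from replicates 2 and 3.

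A set of 266 genes was chosen after seeing the data. Each had at least 20 CPM in uninoculated day 1 replicate 1 and lay over 16-fold above the log2 mean of replicates 2 and 3. The median of the set was 68.16 CPM in uninoculated day 1 replicate 1, against 0.91 and 1.64 CPM in replicates 2 and 3, a gap that follows from this choice. In inoculated day 1 bulbs it was 2.03 CPM in replicate 1 and 12.95 and 17.83 CPM in replicates 2 and 3. In day 7 libraries it was 0.58 to 2.32 CPM without and 8.27 to 15.21 CPM with inoculation.

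**Figure D2:**
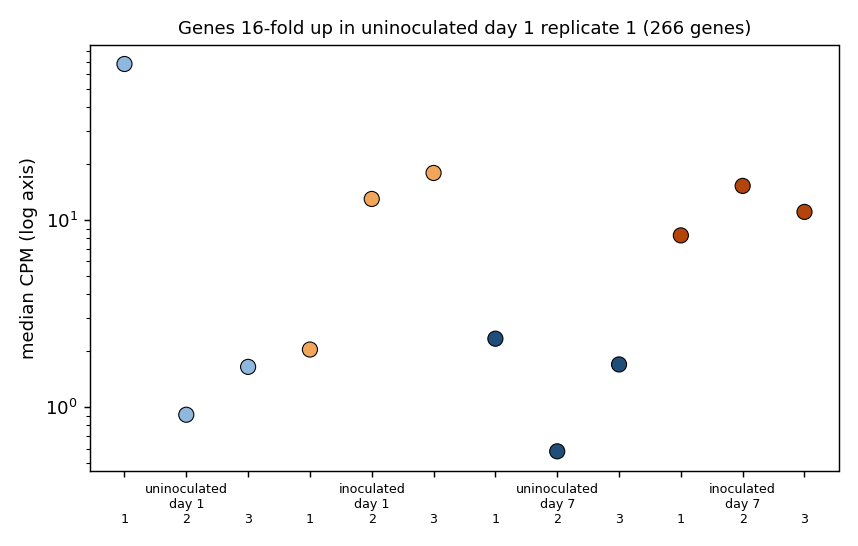
Median CPM (y axis, log scale) of the 266 genes in each of the 12 libraries (x axis, by group and replicate number); each point is 1 library. Uninoculated day 1 replicate 1, on which the genes were chosen, is at 68.16 CPM, and inoculated day 1 replicate 1 at 2.03 CPM is below replicates 2 and 3 of its group.

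At day 1, the question was which transcripts differ between inoculated and uninoculated bulbs. Of 32211 genes tested, 4960 were higher and 4363 lower in inoculated bulbs (28.9%; edgeR quasi-likelihood test, adjusted p under 0.05). The median change was 3.76 among the higher and -1.97 among the lower genes on the log2 scale. Changes of at least 32-fold were fitted for 2187 higher and 830 lower genes. Some had few or no reads in the lower group, where the fitted size depends on the prior count. Such fits also enter the medians. The higher genes took 5.5% ± 0.14 of the reads in uninoculated bulbs and 26.2% ± 2.22 in inoculated bulbs, and the lower genes 27.6% ± 3.85 and 8.7% ± 1.83 (SD, n = 3); these genes were chosen on the same libraries. Of the 100 most abundant genes, 27 were higher and 21 lower.

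The reference gene g24394 rose from 0.368 ± 0.199 CPM in uninoculated to 7350 ± 2830 CPM in inoculated day 1 bulbs (SD, n = 3), a log2 fold change of 14.26 (SE 0.62, edgeR adjusted p = 8.82e-07). The assembled locus XLOC_481819 rose from 0.251 ± 0.0851 to 3830 ± 339 CPM (log2 fold change 13.86, SE 0.44, edgeR adjusted p = 1.74e-07). Among genes that fell, g13620 went from 2270 ± 744 to 5.14 ± 4.24 CPM (log2 fold change -8.79, SE 0.79, edgeR adjusted p = 4.41e-05). The gene g412016 went from 210 ± 78.1 to 0.696 ± 1.2 CPM (log2 fold change -8.24, SE 2.04, edgeR adjusted p = 0.0127). Its inoculated reads lay in replicate 1 alone (2.09, 0 and 0 CPM in replicates 1, 2 and 3). Without that library the fitted log2 fold change was -14.97, against a group at 0 reads and so no bound. The call of g412016 was lost without the low-count filter (adjusted p = 0.0546; range over its alternatives 0.00128 to 0.0546). All 4 genes share at least some reads with other genes. How far their levels depend on how RSEM divided those reads was not measured. With the libraries of day 1 alone, 2892 genes were higher and 2125 lower. Without both day 1 libraries numbered 1, an alternative chosen after seeing the data, 8537 were higher and 6499 lower.

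Reference models and assembled loci both contributed. Of 21853 reference models tested at day 1, 3040 were higher and 3234 lower. Of 9567 assembled coding loci, 1786 were higher and 996 lower. Of 791 lncRNA loci, 134 were higher and 133 lower. As a list chosen after seeing the data, the lncRNA loci showed no detectable shift in a common direction against other genes at day 1 (camera p = 0.5335, or 0.8608 with an estimated correlation). Camera does not test how often loci are called: 33.8% of the lncRNA loci were, against 28.8% of the other genes. Genes with whole counts were called about as often as genes with shared reads: 1793 higher and 1301 lower of 11178 (27.7%), against 3167 higher and 3062 lower of 21033 (29.6%).

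At day 7, the same question gave 5251 genes higher and 4728 lower in inoculated bulbs (31.0%; edgeR quasi-likelihood test, adjusted p under 0.05). The median change was 3.47 among the higher and -1.71 among the lower genes on the log2 scale, and changes of at least 32-fold were fitted for 2202 higher and 689 lower genes. As at day 1, these values include fits against few or no reads, whose size depends on the prior count. The higher genes took 4.5% ± 0.12 of the reads in uninoculated bulbs and 29.3% ± 1.78 in inoculated bulbs, and the lower genes 32.5% ± 0.37 and 10.6% ± 0.26 (SD, n = 3), again chosen on the same libraries. Of the 100 most abundant genes, 24 were higher and 22 lower.

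The genes g24394 and XLOC_481819 again rose most under the naming rule. The level of g24394 went from 0.485 ± 0.171 to 12000 ± 841 CPM (log2 fold change 14.58, SE 0.62, edgeR adjusted p = 8.32e-07). That of XLOC_481819 went from 0.342 ± 0.0682 to 7400 ± 1640 CPM (log2 fold change 14.37, SE 0.44, edgeR adjusted p = 1.33e-07). The gene g13620 fell from 3430 ± 431 to 8.47 ± 2.06 CPM (log2 fold change -8.66, SE 0.79, edgeR adjusted p = 4.58e-05), and g514720 from 51.7 ± 8.91 to 0.313 ± 0.542 CPM (log2 fold change -7.36, SE 1.13, edgeR adjusted p = 0.00193). The inoculated reads of g514720 lay in replicate 1 alone (0.939, 0 and 0 CPM), and without that library its fitted log2 fold change was -12.95, again against 0 reads and no bound. These 4 genes also share reads with other genes. Of the lncRNA loci, 112 were higher and 122 lower (29.6% called, against 31% of the other genes). As a list they showed no detectable shift in a common direction against other genes (camera p = 0.1806, or 0.7072 with an estimated correlation). With the libraries of day 7 alone, 7724 genes were higher and 6155 lower, more than in the joint fit, where day 1 alone gave fewer. The similar shares called at day 1 and day 7 therefore belong to the joint fit. Without both day 1 libraries numbered 1, the day 7 counts were 7944 higher and 6626 lower. No day 7 library changed there, so that shift came through what the joint fit shares: the filter, the normalization and the estimated spread. Which of these moved the counts was not tested.

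The inoculation effects of both days were then compared across genes. At both days 3425 genes were higher and 2709 lower, where independent lists of these sizes would share 809 and 640. Only 85 genes were called in opposite directions, a count that depends on the libraries. It was 55 without inoculated day 1 replicate 2, 41, 41 and 50 without uninoculated day 7 replicates 1, 2 and 3, 48 and 53 without inoculated day 7 replicates 1 and 2, and 198 without both day 1 libraries numbered 1. It was 44 without the low-count filter, 55 under the replicate block and 30 with whole counts. The log2 fold changes of day 1 and day 7 correlated across genes with Pearson r = 0.788 and Spearman rho = 0.675; genes are not independent replicates, and the day 1 and day 7 effects used separate control libraries. Of the day 1 calls, 65.8% were also called in the same direction at day 7, and 61.5% of the day 7 calls were also called in the same direction at day 1. Calls at 1 day only numbered 3104 for day 1 and 3760 for day 7, but the test of the difference between days passed in 105 and 22 of them.

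**Figure D3:**
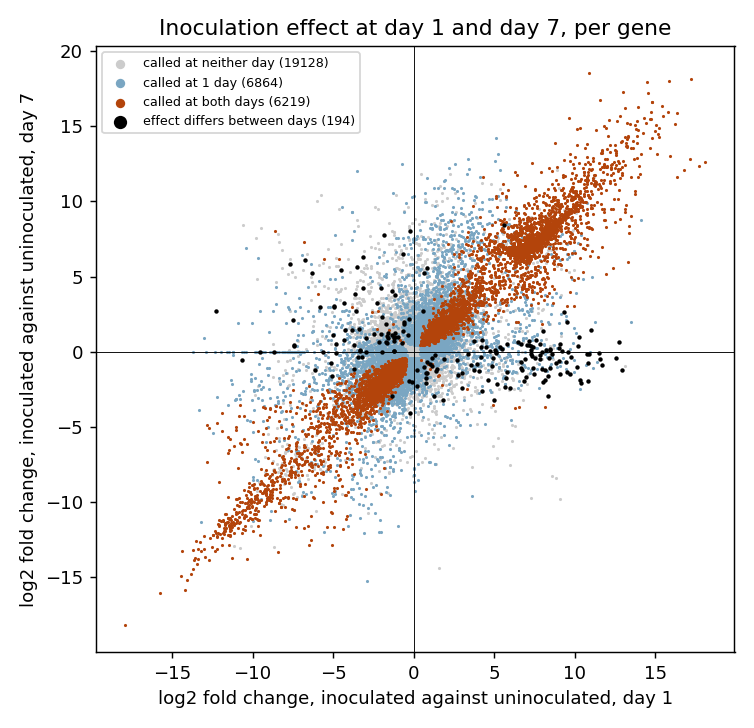
Fitted log2 fold change of inoculated against uninoculated bulbs at day 1 (x axis) and day 7 (y axis); each point is 1 of 32211 tested genes, coloured by calls, with black points for the 194 genes whose effect differed between days. Most genes called at both days lie along the diagonal, and many black points lie near 0 at day 7.

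The effect itself differed between days for 194 genes, 76 with a higher and 118 with a lower effect at day 7 (edgeR interaction contrast, adjusted p under 0.05). Among those with a lower effect at day 7, XLOC_086658 had 0 reads in uninoculated day 1 bulbs, 19.1 ± 1.67 CPM in inoculated day 1 bulbs, and 25.6 ± 4.27 and 24.2 ± 4.45 CPM in uninoculated and inoculated day 7 bulbs. The gene g269275 had 0 reads in uninoculated day 1 bulbs, 21.3 ± 2.06 CPM in inoculated day 1 bulbs, and 59.5 ± 11.3 and 32.1 ± 9.95 CPM at day 7. Among those with a higher effect at day 7, g528852 fell from 20.6 ± 1.57 to 0.184 ± 0.0975 CPM at day 1. It had 0 reads in uninoculated and 0.451 ± 0.245 CPM in inoculated day 7 bulbs. The gene g215620 fell from 22.1 ± 10.7 to 0.102 ± 0.0518 CPM at day 1. It also had 0 reads in uninoculated day 7 bulbs, and 0.359 ± 0.155 CPM in inoculated ones (SD, n = 3 throughout). Both genes were thus near 0 in every group except uninoculated day 1 bulbs. The edgeR adjusted p of the difference was 0.000124, 0.000124, 0.00137 and 0.00214 in that order. Of these 4 only g215620 has whole counts. Leaving out 1 library lowered the 194 calls by over 1.5 times for 9 of the 12 libraries, namely inoculated day 1 replicates 2 and 3 (89 and 109), uninoculated day 1 replicate 3 (110), uninoculated day 7 replicates 1, 2 and 3 (81, 93 and 100) and inoculated day 7 replicates 1, 2 and 3 (103, 92 and 114). DESeq2 called 628 higher and 668 lower. Without both day 1 libraries numbered 1 there were 336 higher and 607 lower, and 189 of the 194 genes were still called. As labelled, 2.1% of the lncRNA loci and 0.6% of the other genes were called, a contrast that was not tested.

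Between day 1 and day 7, uninoculated bulbs changed in 891 genes, 521 higher and 370 lower at day 7 (edgeR, adjusted p under 0.05). XLOC_506973 rose from 0.200 ± 0.131 to 36.0 ± 4.64 CPM (log2 fold change 7.44, SE 0.40, edgeR adjusted p = 2.99e-05). The gene g194014 rose from 0.267 ± 0.231 to 35.8 ± 10.2 CPM (log2 fold change 7.03, SE 1.37, edgeR adjusted p = 0.0257). Its call was lost without the low-count filter, under the replicate block, and without any 1 of uninoculated day 1 replicates 1 and 3 and uninoculated day 7 replicates 1, 2 and 3 (adjusted p from 0.0614 to 0.0844; over all its alternatives 2.67e-08 to 0.0844). The lncRNA locus XLOC_353638 fell from 61.8 ± 34.7 to 0.179 ± 0.118 CPM (log2 fold change -8.37, SE 1.22, edgeR adjusted p = 0.00745), and XLOC_264532 from 58.2 ± 28.5 to 0.202 ± 0.130 CPM (log2 fold change -8.14, SE 0.64, edgeR adjusted p = 0.000261). All 4 share reads with other genes. The count fell to 421 without uninoculated day 1 replicate 3 and to 334, 372 and 367 without uninoculated day 7 replicates 1, 2 and 3, and DESeq2 called 1484 higher and 1542 lower. When the day 1 libraries numbered 1 exchanged groups, a refit chosen after seeing the data, 20 genes were higher and 5 lower. As labelled, 8% of the lncRNA loci and 2.6% of the other genes were called, a contrast that was not tested.

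In inoculated bulbs edgeR called 0 genes between day 1 and day 7, where 3256 genes had an unadjusted p under 0.05 and the smallest adjusted p was 0.0681. DESeq2 called 655 genes and limma-voom 31. Without both day 1 libraries numbered 1, edgeR called 902 genes higher and 1613 lower at day 7, so the count of 0 depends on these libraries. With these libraries exchanged between groups, 298 genes were higher and 771 lower. Leaving out inoculated day 1 replicate 1 alone gave 2 genes, and uninoculated day 1 replicate 1 alone 0 genes.

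More genes were detected in inoculated bulbs. With a minimum expected count of 1, uninoculated and inoculated day 1 libraries held 39985 ± 554 and 42899 ± 539 genes, and day 7 libraries 39572 ± 1367 and 44188 ± 766 (SD, n = 3). Each day's difference had the smallest p that 3 against 3 can give (two-sided exact permutation test, p = 0.1). Permuting within days over both days, the mean difference of 3765 genes had p = 0.005 (exact permutation test), also the smallest possible. After thinning the libraries to one total, a step chosen after seeing the data, the differences were 2785 genes at day 1 and 4296 genes at day 7. With a minimum expected count of 10, chosen after seeing the data, they were smaller, 1059 and 1510 genes (944 and 1389 after thinning), with the same p of 0.1 at each day and 0.005 over both days. The percent of reads in genes with whole counts differed by -4.1 percentage points at day 1 and -4.73 at day 7, inoculated minus uninoculated (exact permutation test, p = 0.2 and 0.1, and 0.01 over both days). On average a larger part of the reads of inoculated libraries was thus in genes that share reads, which RSEM divides; how far this adds to detection was not tested.

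**Figure D4:**
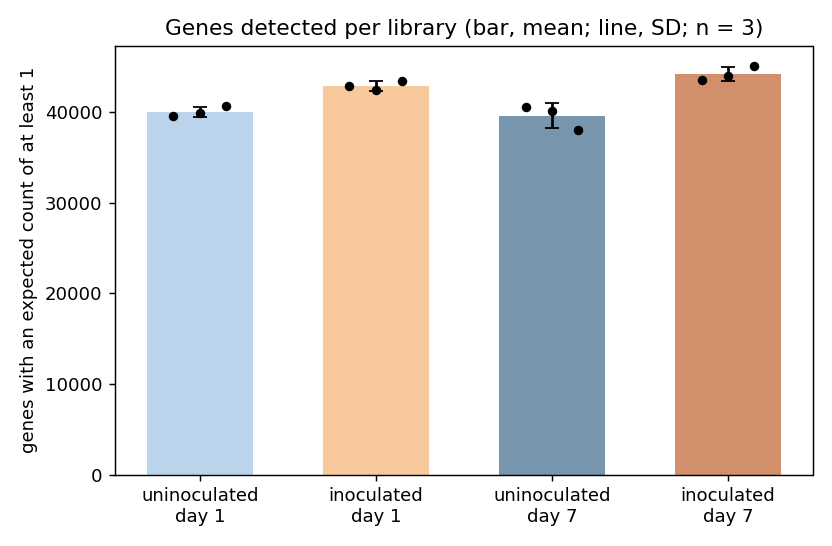
Genes with an expected count of at least 1 per library (y axis) in the 4 groups (x axis); bars are means, lines are SD, points are libraries (n = 3). Inoculated means are 42899 and 44188, above the uninoculated means of 39985 and 39572.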

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

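The weighing of a difference between bulbs and the refit with exchanged libraries were chosen after the result was seen. The splits within days were written before, and the splits within treatments after. The limit for shared reads was written before that test was run, but for a profile of genes found in these results.

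The inoculation effect differed between day 7 and day 1 for 194 genes, by a test of the difference itself. The named genes stand out for the same reason: the log2 difference of the effect, day 7 minus day 1, was 12.87 for g528852, 13.48 for g215620, -11.59 for XLOC_086658 and -12.56 for g269275. In each of these 4 genes a whole group had 0 reads, so the fitted differences depend on the prior count and are no bounds.

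Many of the 194 genes shared a profile: 79 had under 10 reads over the 3 uninoculated day 1 libraries and at least 10 in each of the other groups. Only 9 genes were under 10 reads only in uninoculated day 7 bulbs, 3 only in inoculated day 1 bulbs and 0 only in inoculated day 7 bulbs. The limit set beforehand for reads shared between near-identical copies as the cause was under 10% of the 79 genes with whole counts. The share was 41.8%, beside 34.7% of all tested genes, which argues against shared reads as the whole cause. A difference between the bulbs of the groups other than treatment stays open for these 79 genes, since no value in the tables separates bulb from group. A change in uninoculated bulbs between the days, a biological difference that the design names, also stays open.

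Of 100 splits of the day 1 and day 7 libraries drawn with the real one, 2 called as many genes for the difference between days, the real one included. The real count was 194 and the highest other 10946. These splits mix the treatments within days, so low counts are built into most of them and the 2 say nothing about chance. A second set of 100 splits, the real one included, exchanged libraries between days within each treatment: 6 called as many genes as the real 194, and the highest other called 482. All 6 left the uninoculated bulbs at their own days and so kept part of what is tested. Of the 5 besides the real one, 4 also reversed the days of most or all inoculated bulbs. Other splits that kept the uninoculated days and reversed most inoculated bulbs called fewer genes than the real 194, down to 93. Such a reversal therefore did not raise the count in every split, and its part in the higher counts was not tested. The 12 splits with the uninoculated bulbs at their own days called 93 to 482 genes and the others at most 6, but mixing days also widens the spread. Neither set of splits therefore says whether chance can be excluded for the 194 genes. In the first set, the split with 10946 took uninoculated day 1 replicate 1 with inoculated day 1 replicates 2 and 3 as the uninoculated group. It thereby reversed the treatment in most day 1 libraries, so the treatment effect itself enters its count. Another drawn split that reversed as many, with uninoculated day 1 replicate 1 and inoculated day 1 replicates 1 and 2 as the uninoculated group, called 0 genes, which points to a structure of the day 1 libraries. When the day 1 libraries numbered 1 exchanged groups in the other orientation and day 7 stayed as labelled, 3 genes had a higher and 8 a lower effect at day 7. The change between days in that refit had 20 higher and 5 lower genes in uninoculated bulbs (521 and 370 as labelled) and 298 and 771 in inoculated bulbs (as labelled 0 by edgeR, with 3256 at an unadjusted p under 0.05, 655 by DESeq2 and 31 by limma-voom). By construction such an exchange also puts a library with reads into groups near 0 reads, as in the 79 genes. With both libraries left out, 189 of the 194 genes were still called.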

How the results depend on the processing

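Removal of both day 1 libraries numbered 1, the restriction to whole counts, and the lncRNA list tests were chosen after seeing the data. The cause of each shift was not tested except where fewer genes or a stricter threshold make a lower count by construction. Using fewer libraries lowered some counts and raised others, as in the fits of day 1 and day 7 alone. Apart from the values given here, 243 values of the main results lay within 1.5 times (counts) of those reported.

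For inoculated against uninoculated bulbs, at day 1 the higher and lower genes numbered 2892 and 2125 with the libraries of that day alone, 1989 and 1271 among genes with whole counts, 3041 and 2163 at an adjusted p under 0.01, and 2808 genes were higher with a minimum of 5 CPM in 3 libraries. Without both libraries numbered 1, 8537 were higher. At day 7 the numbers were 2221 and 1361 with whole counts, 2986 and 2358 at 0.01, 3118 higher with 5 CPM, and 7944 higher without both libraries. Leaving out 1 library gave 3886 to 6624 higher and 2725 to 5056 lower genes at day 1, and 3872 to 6807 and 3164 to 5271 at day 7.

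For the difference between days, higher and lower genes numbered 628 and 668 with DESeq2, 162 and 192 with limma-voom, 302 and 205 on log2(FPKM + 1), 275 and 247 on log2(FPKM + 0.1), 12 and 42 with whole counts, 336 and 607 without both libraries, 15 and 41 at 0.01, and 74 were lower with 5 CPM. Leaving out 1 library gave 28 to 84 and 53 to 136. For uninoculated bulbs over time they numbered 1484 and 1542 with DESeq2, 793 and 737 on log2(FPKM + 1), 152 and 101 with whole counts, and 149 and 82 at 0.01; 786 were higher with limma-voom and 654 lower on log2(FPKM + 0.1). Leaving out 1 library gave 229 to 756 and 105 to 571. For inoculated bulbs over time they numbered 356 and 299 with DESeq2, 25 and 6 with limma-voom, 72 and 30 on log2(FPKM + 1), 46 and 25 on log2(FPKM + 0.1), 1 and 1 without a composition factor, 1 and 1 without the low-count filter, 1 and 1 with 5 CPM, 0 and 1 with whole counts, and 902 and 1613 without both libraries. Leaving out 1 library gave 0 to 2 higher and 0 lower.

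Genes called at both days numbered 1803 higher with 5 CPM, 1481 higher and 748 lower with whole counts, and 5911 and 4355 without both libraries; leaving out 1 library gave 2947 to 4605 and 1916 to 3270. Genes called in opposite directions numbered 44 without the low-count filter, 55 under the replicate block, 30 with whole counts, 198 without both libraries, and 41 to 115 with 1 library left out. Pearson r of the effects was 0.635 without the low-count filter and 0.733 to 0.797 with 1 library left out. The rotation test fry of limma gave the lncRNA loci the opposite direction from camera, with 0.5119 at day 1 and 0.9276 at day 7 as its p, neither past the threshold. The fry p for changes in any direction was 3.193e-15 and 5.449e-13, but that version does not compare the loci with other genes. Named genes kept their direction in 272 of 272 values, 8 of which missed the threshold (1 for g412016, 7 for g194014). They were chosen for large changes or a small adjusted p in these same libraries, so an unchanged direction was largely built in.

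The replicate numbers did not pair the bulbs: over 18 same-numbered pairs the correlation of deviations ran from -0.49 to 0.14, and 2 libraries correlated best with their own number. With the replicate number as a block, the difference between days had 16 higher and 42 lower genes and uninoculated bulbs over time 230 and 125; the other comparisons stayed within 1.5 times. Removing both day 1 libraries numbered 1 moved the median of all genes at day 1 to 0.124 on the log2 scale; the other settings listed with a median stayed under 0.1. Genes changed by 1 on the log2 scale were recovered in 2% of cases at day 1 and 0% at day 7 in simulation; few genes were changed there, which makes the adjusted threshold stricter than in the real comparisons, so these shares do not say what was detectable in them.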

Other observations

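The tests in this part were chosen after the results were seen, except the counts of splits. The limit for library depth was written before that test was run, but for libraries already seen to stand apart.

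At day 1 and at day 7 a set of genes went from no signal to a clear level or the reverse. Counting genes with at least 10 CPM in each library of one group and under 10 reads over the other group, 208 genes appeared and 115 disappeared in inoculated bulbs at day 1, and 279 and 130 at day 7. Between the days, 29 appeared and 19 disappeared in uninoculated bulbs, and 2 and 0 in inoculated bulbs.

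Taking both days together, 98 of 13162 genes with at least 100 reads in all 6 uninoculated libraries were silent in the 6 inoculated ones. Silent means an expected count under 1 in each library. All 98 share reads with other genes, while 0 of 4215 genes with whole counts were silent (an upper limit of 0.071% from 3 counts), where the rate among genes with shared reads would give 46.2. Loss of transcripts at one rate in genes with and without shared reads is argued against by Fisher's exact test across genes (p = 6.86e-17). The size of that p is uncertain, since genes that share reads are not independent. Only they can have counts clearly between 0 and 1, so the rule for silent genes is also wider for them. A candidate explanation is that RSEM gave the reads of near-identical copies to one copy in uninoculated and to another in inoculated bulbs, which the tables allow. Bulbs of the treatments that carry different copies or alleles cannot be told apart from this without genotypes or reads: in the opposite direction 114 of 13341 genes were silent in the 6 uninoculated libraries, 4 of them with whole counts. A transcript missing from a table was taken as 0, and whether all libraries were counted against one set of transcripts is not given in the sources used here.

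Replicate 1 of both day 1 groups stood apart: 981 genes in uninoculated and 966 in inoculated replicate 1 lay 8-fold from the mean of replicates 2 and 3 (1947 in all), against 142 to 555 in the other libraries. Depth is argued against, since thinning to one total left 1962. Exchanged labels or mixed RNA are argued against by 1659 genes at least 8-fold apart between all other inoculated and uninoculated libraries. Of these, 76.0% lay near the mean of the labelled treatment in both libraries and 2.53% near that of the other treatment in both. The rest met neither description. Separately, 87 genes had at least 100 CPM in all inoculated libraries, replicate 1 included by choice, and under 1 CPM in uninoculated day 1 replicates 2 and 3. In uninoculated replicate 1 these 87 genes had a median of 0.002% of their level in inoculated replicate 1. A difference between bulbs in one set of genes, seen at both treatments, stays open, since each bulb gave 1 library: of 266 genes at least 16-fold up in uninoculated replicate 1, 89.5% were lowest in inoculated replicate 1, but genes chosen on one library move together and give no independent test. Their median was 68.16 CPM in uninoculated day 1 replicate 1 and 2.03 CPM in inoculated day 1 replicate 1, against 0.91 and 1.64 CPM in uninoculated and 12.95 and 17.83 CPM in inoculated replicates 2 and 3; which condition of the bulbs they follow was not tested.

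The separation of these libraries was not limited to the 266 genes. When these libraries exchanged groups, 5233 genes were called at day 1, of which 641 were also called as labelled (1515 by independent lists). Of the 5233, 1410 were also called at day 7 (1621 by independent lists), 1403 of them in the day 7 direction. Among those called only after the exchange it was 985 of 991. Replicates 2 and 3 of each group stay in place in the exchange, so agreement in direction is partly built in. No value without that overlap was computed. The exchange also puts a library of the other treatment into each group, which widens the spread of genes with a treatment effect. An overlap below that of independent lists is therefore partly built in as well. Among 5095 genes called at day 7 with a difference of 1 to 3 between the day 7 group means of log2(CPM + 0.1), taken without the model, uninoculated day 1 replicate 1 lay at a median of 0.40 of the way from the uninoculated to the inoculated day 7 mean, against 0.05 and 0.13 for replicates 2 and 3. Inoculated day 1 replicate 1 lay at 0.84, against 1.01 and 1.02. Among 2202 genes with such a difference of 3 to 5 and 1163 with at least 5, uninoculated replicate 1 lay at 0 and inoculated replicate 1 at 1.00, each with its own group.

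Other splits of the libraries were compared for each count of calls. For the 3 against 3 comparisons there are 10 splits, too few for a share under 0.05. At day 1, 1 of 10 splits called as many genes as the real 9323, and the highest other was 5233, the exchange just described. At day 7, 1 of 10 did, with 9979 in the real split and 1 in the highest other. For day 7 against day 1, 1 of 10 did in uninoculated bulbs (891, highest other 1) and 10 of 10 in inoculated bulbs (0, highest other 6), where a real count of 0 makes every split match by construction.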
